A study of Mus musculus with 4 samples.

How the data were processed

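Gene expression was measured on 4 Illumina bead arrays, 1 for each of 4 samples of primary mouse keratinocytes isolated from newborn animals. Per the labels, the cells came from the 129 background and carried a Pou5f1::GFP transgene, a fluorescent reporter of the Pou5f1 gene. The series' design text states that the cells had been transduced with reprogramming transcription factors, without naming the factors. They were grown without or with 2.5 uM DAPT, a small-molecule inhibitor of gamma-secretase, the protease that releases the active intracellular part of Notch receptors. RNA was collected on day 4 or day 7. Each of the 4 groups (no DAPT on day 4, DAPT on day 4, no DAPT on day 7, DAPT on day 7) holds 1 array. Groups were taken from the sample titles, because the treatment field reads DAPT for all 4 samples, including the 2 whose titles say no DAPT. Per the labels' protocols, RNA was extracted with Trizol LS, and biotin-labelled cRNA was made with a MessageAmp kit.

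The deposited table of non-normalized values holds the intensity of each probe on a linear scale, per the file headers. A detection p-value stands beside each intensity in the authors' deposited table, and a low value marks a signal above background. BeadStudio is named in the submitters' processing notes; its version is not given in the sources used here. Background had been subtracted before deposit, as inferred from the values: probes with a detection p near 0.5 averaged between -0.18 and 0.38, and between 5177 and 5847 of the 25697 probes on an array lay below 0. A second deposited table holds the authors' normalized intensity per probe, also on a linear scale. Its normalization method is not given in the sources used here, and its column medians lay between 24.7 and 26.0. Each of its columns had a rank correlation of at least 0.992 with the non-normalized column of the same sample.

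From the non-normalized intensities, neqc of limma 3.58.1 in R 4.3.3 corrected the background with negative controls inferred from the detection p, added an offset of 16, normalized the 4 arrays together by quantiles and took log2. Probes were named through the platform annotation: 23978 of the 25697 had 1 gene symbol, none had several and 1719 are unnamed here. The Entrez identifiers of 23962 probes were found in the RefSeq gene table of assembly GRCm38.p6, which updated 0 symbols. The array's own genome build is not given in the sources used here, so no coordinates are printed. Of the 16593 genes measured, 4777 had more than 1 probe, and each was represented by the probe with the highest mean over the 4 arrays. A gene entered a comparison if its detection p was under 0.01 on at least 1 of the 2 arrays compared. Where the dimmer array did not detect the probe, the difference is given as a lower bound, "at least N-fold", or, where small, as the log2 difference. The bound is taken against the higher of the lowest detected signal on that array and the probe's own signal. Where the probe's own signal is the higher, the bound is the measured ratio. Counts, lists and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

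With 1 array per group, a difference between 2 arrays has no replicate error, and no p-value is given for it. Genes were counted at a difference of at least 2-fold. The 2 comparisons of DAPT with no DAPT share no array, so their agreement was set beside the number expected of independent lists, n1 x n2 / N. That number takes every gene as equally likely to pass, so genes of variable signal can exceed it in any direction. The comparison of DAPT on day 4 and the comparison of day 7 with day 4 without DAPT share the untreated day 4 array, so a signal particular to that array enters both. The one test was an additive limma model with day and DAPT over the 4 arrays, with Benjamini-Hochberg adjustment over 10359 genes detected on at least 1 array and a threshold of 0.05. It leaves 1 residual degree of freedom per gene, which is the difference between the gene's DAPT effects on the 2 days. The test thus cannot separate noise from a DAPT effect that depends on the day. The estimated prior degrees of freedom were infinite, so every gene was tested with the same spread, an SD of 0.384 on the log2 scale, and its p-values measure only the spread among these 4 arrays, whose cultures are not stated to be independent. On simulated data for the effect of DAPT in 10359 genes, of which 200 were changed, this model recovered 11% of changes of 1 log2 unit, 98% of 2 units and 100% of 3 units, with 0, 7 and 9 false calls. The simulated noise was independent and normal with this same SD for every gene, without a DAPT effect that depends on the day. These figures hold for that setting, which is the model's own assumption, and not for the real arrays. The counting and list steps were also tested on simulated data.

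Before the data were examined, 23 gene lists were fixed: Notch targets, Notch pathway components, reprogramming factors, pluripotency, basal keratinocyte, spinous, granular and cornified, wound and stress keratinocyte, simple epithelial and junction, p53 target, cell cycle inhibitor and senescence, S phase, G2 and M phase, mesenchymal and fibroblast, melanocyte, immune cell, endothelial, interferon response, inflammatory cytokine and chemokine, unfolded protein and amino acid stress, sterol synthesis, hypoxia and glycolysis, and antioxidant response genes. The median log2 difference of a list's detected members was placed among 10000 random lists of the same size matched on mean expression in 20 bins; the percentile describes these arrays and is no p-value. Named genes followed a rule fixed at the same time: up to 10 each way among genes at least 2-fold different in the same direction on both days, the 5 highest and 5 lowest with DAPT on each day, the 6 highest and 6 lowest between the days without and with DAPT, all Notch targets and reprogramming factors, Cdkn1a and Trp63, up to 4 members of each other list, and up to 5 genes each way that passed the additive test. Other members of a list named as examples were chosen after their values were seen.

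Alternatives tried were quantile normalization without background correction and the authors' normalized values, each with values under 16 set to 16, scaling to a common median in place of quantile normalization, an offset of 50, detection on every array compared, no detection filter, a detection threshold of 0.05, the mean over a gene's probes, a threshold of 1.5-fold, and, for the additive test, the compared factor alone, the same with each array left out, and a prior that follows intensity. A count that requires every detected probe of a gene to pass was added after seeing the data. Precision is limited by the number of arrays. No sample was left out.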

Results

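Transduced primary mouse keratinocytes were profiled on 1 array per group, without and with the gamma-secretase inhibitor DAPT, on day 4 and day 7. Mean intensity was 472 without DAPT and 365 with DAPT on day 4, and 323 without and 416 with DAPT on day 7. The arrays detected 14145, 12669, 12281 and 13627 of 25697 probes, in the same order. The array brightness thus differed with DAPT in opposite directions on the 2 days, by -0.37 on day 4 and 0.36 on day 7 on the log2 scale, and by -0.00 in their mean. No group has a replicate, so the differences below compare single arrays unless the additive test is named. As a guide to measurement error, the SD between 2 detected probes of a gene was 0.49 for the difference with DAPT on day 4 and 0.34 on day 7, on the log2 scale.

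The first question is how genes of the Notch pathway stood on the arrays. Of 8 Notch target genes, 3 were detected. Hes1 differed by -0.80 with DAPT on day 4 and by 0.12 on day 7, and Nrarp, which encodes a feedback inhibitor of Notch, by -0.30 and -0.90. Hey1 was detected on 1 array of each pair and differed by -0.31 on day 4 and 0.03 on day 7. Both lay within the SD between probes (0.49 and 0.34), so they settle no direction. Hes5, Hes7, Hey2, Heyl and Dtx1 were not above background on any array. The 3 detected targets had medians of -0.31 on day 4 (percentile 13.1) and 0.03 on day 7 (percentile 54.6). Their median over the mean of both days was -0.34, at percentile 2.25 of the random lists. With 3 genes this is the value of Hes1 alone, whose differences had opposite signs on the 2 days. It was not tried under the alternatives. The 15 Notch pathway components detected on day 4 had a median of 0.04 (percentile 46.9), and the 13 detected on day 7 one of 0.00 (percentile 70.5). With median scaling the day 7 median of the targets was -0.04 and the day 4 median of the components -0.07. Aph1a, a subunit of gamma-secretase, differed by -1.81 on day 4 and 1.05 on day 7, Notch4 by -0.80 and -0.46, and Dll3 by 0.97 and -0.20. Rfng, a modifier of Notch receptors, was at least 2.03-fold lower with DAPT on day 4.

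On day 4, genes of the outer epidermis were higher with DAPT. Of 17 detected granular and cornified layer genes, 8 were at least 2-fold higher and 0 lower, with a median of 0.93 (percentile 100). Rptn, which encodes repetin of the cornified envelope, was higher by 2.66, Lce1c by 2.81, Sprr1b by 2.11, and Klk7, a protease of skin shedding, by 1.81. The highest gene was Stfa1, a cysteine protease inhibitor, at 3.47, followed by Lce1a2 at least 7.55-fold, Sprr2i at 2.86, Lce1c and Rptn. Stfa2 and Stfa3, close relatives of Stfa1 whose probes may not separate the family, were at least 2.45-fold and 2.34-fold higher. Not all differentiation genes followed: Ivl, which encodes involucrin, differed by -1.89 and Tgm1 by -0.58. The 6 detected spinous layer genes had a median of 0.56 on day 4 (percentile 97.6) and 0.30 on day 7 (percentile 97). With no detection filter the day 4 percentile was 54.8, and with detection required on both arrays the day 7 median was -0.37. The lowest genes were Rab1b at -2.66, Igfbp3, a secreted binder of insulin-like growth factors, at -2.66, Syngr2 at -2.56, Eef2, a translation elongation factor, at -2.51 and Car2 at -2.24. Other probes disagreed for 2 of them: those of Rab1b ranged up to 0.12 and those of Car2 up to 1.16.

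Of the cell cycle lists, the 14 detected G2 and M phase genes had a median of 0.47 on day 4 (percentile 98.0). Of these, Ube2c at 1.06 and Kif11 at 1.03 passed 2-fold, while Cdk1 and Birc5 stood at -0.40 and -0.31. That percentile was 94.6 with the mean over a gene's probes, 96.3 with the authors' values and 96.6 without background correction. The 15 detected S phase genes had a median of 0.15 (percentile 60.1), which was -0.18 with median scaling, and 0 of them passed 2-fold. Cdkn1a, the cell cycle inhibitor p21, differed by -1.02, with its 3 probes between -1.75 and -0.76. The list of other cell cycle inhibitors and senescence genes had a median of -0.43 (percentile 0.700), with Igfbp3, Cdkn2a at -1.23 and Cdkn2d at -1.03 at least 2-fold lower; with no detection filter the median was -0.02 (percentile 29.3). Altogether 735 of 9913 genes differed at least 2-fold on day 4, 378 higher and 357 lower with DAPT. Median scaling gave 199 higher and 678 lower, and it shifted the median of all genes by -0.18 on day 4 and by 0.22 on day 7.

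On day 7, cell cycle and interferon response genes were higher with DAPT and pigment cell genes lower. The 13 detected G2 and M phase genes had a median of 0.90 (percentile 100), with 5 at least 2-fold and 11 at least 1.5-fold higher, among them Cdc20 at 1.26, Nusap1 at 1.15, Birc5 at 1.13 and Cdk1 at 1.07. The 14 S phase genes had a median of 0.46 (percentile 100), with Uhrf1 at 1.26, Tyms at 0.91 (its probes from 0.04) and Mcm5 at 0.74. Of 14 detected interferon response genes, 7 were at least 2-fold higher and 0 lower, with a median of 1.05 (percentile 100): Ifit3 stood at 1.89, Oasl2 at 1.69, Usp18 at 1.62 and Isg15 at 1.54, while Ifit2 stood at -0.29. On day 4 this list had a median of 0.15 (percentile 59.8), which was -0.19 with median scaling, and 6 of its members were below 0. Of 6 melanocyte genes, 4 were at least 2-fold lower on day 7, with a median of -1.27 (percentile 0). The median was -0.76 with no detection filter, -0.74 with an offset of 50 and -2.09 with the authors' values, at percentile 0 in each. The lower genes were the pigment enzyme gene Tyrp1 at -2.24, with its other probe at -0.65, Mlana at -1.49, Dct at least 3.15-fold lower and Pmel at least 2.06-fold lower. On day 4 the melanocyte median was 0.09 (percentile 51.2), and -0.21 with median scaling.

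The outer epidermal genes kept a higher median on day 7, at 0.21 (percentile 99.6), with 5 of 17 at least 2-fold higher and 0 lower. The 14 basal keratinocyte genes had a median of 0.22 on day 7 (percentile 99.7) and 0.24 on day 4 (percentile 82.3), where the mean over probes gave -0.00. Krt5, a keratin of the basal layer, differed by 1.0 on day 4 and 1.70 on day 7, Krt15 by 1.04 and 0.54, and Col17a1, a hemidesmosome collagen, by 1.04 (its probes from 0.22) and 1.15. Trp63, a regulator of epidermal identity, differed by 0.31 and 0.18. Other members were lower, such as Itgb1, an integrin subunit, at -0.69 on day 7 and Itga3 at -0.31 and -0.24, and 9 of the 14 were above 0 on day 7. The highest genes on day 7 were Apod at 2.71, Ifitm1 at least 5.20-fold, Krtdap at 2.44, Stfa1 at 2.42 and the gap junction gene Gjb2 at least 5.29-fold. The lowest were Tyrp1, Akr1c19 at -1.99, Idi2 at -1.83, Dct and Mgp at -1.65. The inhibitor and senescence list had a median of -0.35 (percentile 0.420), with Cdkn2a at -0.74, its other probe at -0.02, and Cdkn1c at -0.71, while Cdkn1a stood at 0.07, with its 3 probes up to 0.90. Igfbp3, the lowest member of the list on day 4, stood at 0.99 on day 7. In total 214 of 9705 genes differed at least 2-fold, 166 higher and 48 lower. Median scaling gave 350 higher and 18 lower, and the authors' values gave 350 and 300.

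**Figure D1:**
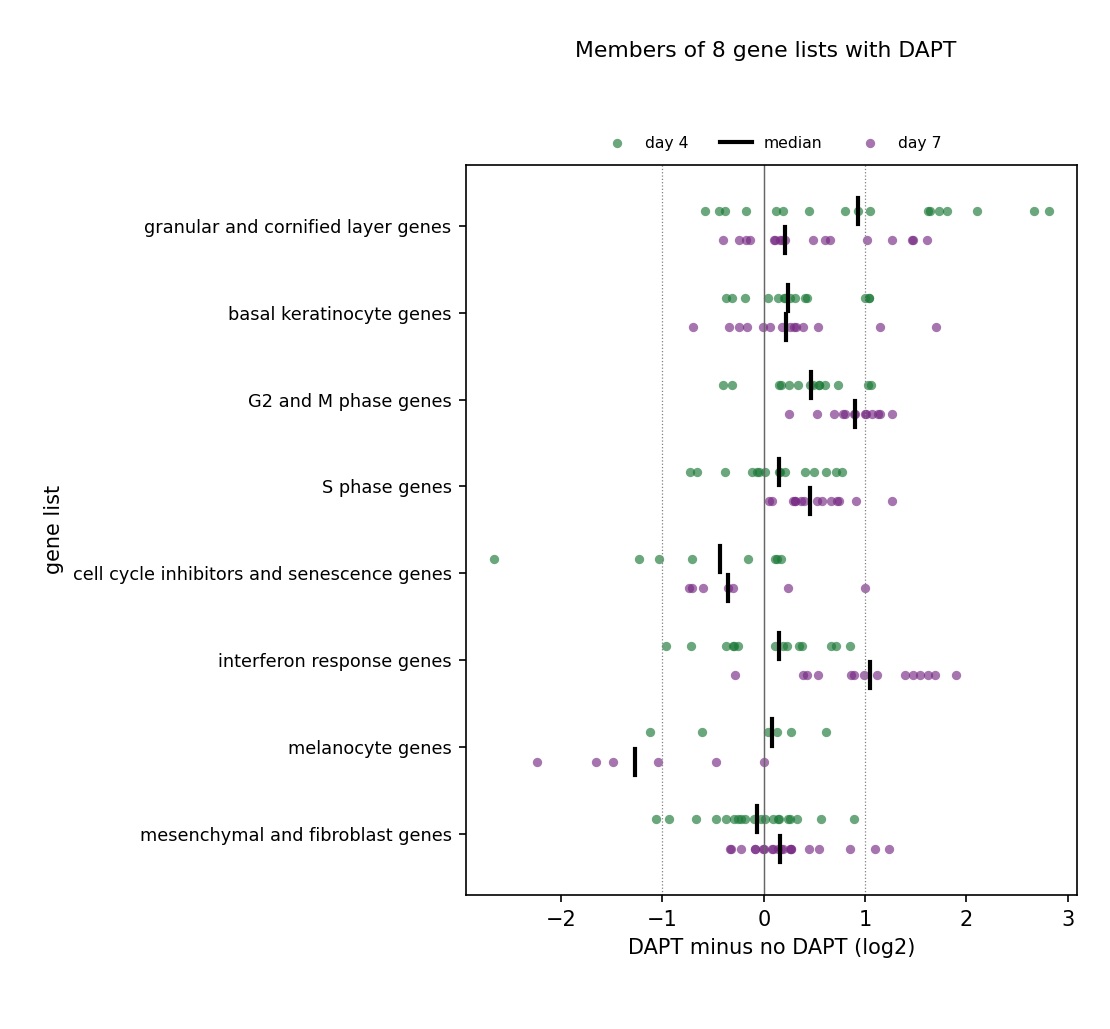
Log2 difference between the DAPT array and the array without DAPT for each detected member of 8 gene lists (points), on day 4 (green) and day 7 (purple), with the list median as a black bar and dotted lines at 2-fold. The granular and cornified list had medians of 0.93 and 0.21, the interferon list 0.15 and 1.05, and the melanocyte list 0.09 and -1.27; the day 4 medians of the S phase, interferon and melanocyte lists were below 0 with median scaling.

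Ranked by the smaller of the 2 days' differences, the first genes with the same direction on both days were Stfa1, Cnfn, Defb4, Rptn and Klk7. Of 9259 genes detected on both days, 19 were at least 2-fold higher with DAPT on each day, where independent lists would share 6.17, and 2 were lower, where 1.61 would be shared. Opposite directions also exceeded this number. Lower on day 4 and higher on day 7 were 49 genes, where 5.98 would be shared, and 3 went the other way, where 1.66 would be. The excess is thus by itself no sign that the days agree. At 1.5-fold the 104 shared higher genes did not exceed the 108 of independent lists, and the 35 shared lower genes fell below the 57.7. Of the shared genes, Stfa1, Cnfn (1.62 on day 4 and 1.61 on day 7), Rptn, Klk7 and Sprr1b were measured on all arrays, and Defb4, a beta-defensin, was higher by 2.46 and at least 2.78-fold. The others of the first 10 were Tgfbr3 (1.45 and 1.31), Prelp (1.25 and 1.9), Krtdap (1.23 and 2.44) and Cep55 (1.40, and at least 2.32-fold). The lower genes were Idi2 (-1.30 and -1.83) and Pmel (at least 2.17-fold and 2.06-fold). Across genes, which are not independent replicates, the differences of the 2 days had a Pearson r of -0.29 and a Spearman rho of -0.32.

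In the additive limma test, 11 genes rose and 1 fell with DAPT over both days, and 203 of 10359 passed an unadjusted p of 0.05, where chance would give 518. The residual of this test is the difference between the 2 days' DAPT effects, which ran against each other (Pearson r of -0.29). That makes the spread wide beside the mean effect, so that fewer genes pass. Stfa1 rose by 2.95 (SE 0.38, adjusted p = 1.77e-10), Rptn by 2.07 (adjusted p = 0.000366), Defb4 by 1.97 (adjusted p = 0.00104), Sprr2i by 1.84 and Krtdap by 1.83 (both adjusted p = 0.00385). The others that rose were Lce1a2, Ifitm1, Sprr1b, Klk7, Cnfn and Prelp, by 1.78 to 1.57, and Idi2 fell by 1.56 (adjusted p = 0.0400). Without DAPT, Lce1a2 on day 4 and Ifitm1 and Defb4 on day 7 were not above background. The fit takes such signals as measured, so the sizes and p-values of these genes are not exact. With detection required on every array, 8 genes rose and 1 fell. Each of the 12 differed in the same direction on both days. Median scaling, no background correction, no detection filter and the mean over probes each left 0 genes at the adjusted threshold. With day left out of the model, 0 genes passed on all 4 arrays and on any 3 of them.

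**Figure D2:**
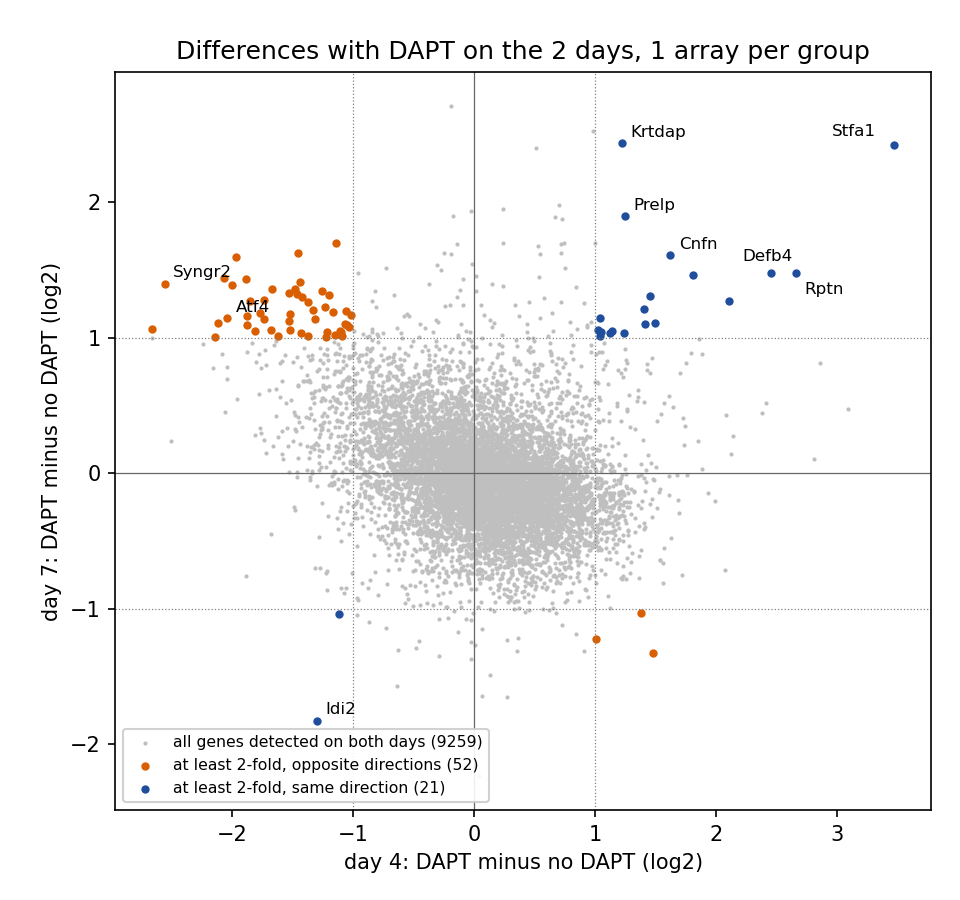
Log2 difference with DAPT on day 4 (horizontal axis) against that on day 7 (vertical axis) for 9259 genes detected on both days, 1 array per group, with dotted lines at 2-fold. Blue points are the 21 genes at least 2-fold different in the same direction and orange points the 52 in opposite directions, of which 49 were lower on day 4 and higher on day 7.

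Of the reprogramming factors, Klf4 was detected on all 4 arrays, Sox2 on 3, and Pou5f1 and Myc on 2, and the probes do not separate transgene from endogenous transcripts as far as the sources say. Sox2 differed by -1.11 with DAPT on day 4 and by -0.28 on day 7, where the DAPT array did not detect it. Pou5f1 was detected on 1 array of each pair, and differed by -0.01 on day 4 and 0.33 on day 7. Both Pou5f1 values and the day 7 value of Sox2 lay within the SD between probes (0.49 on day 4 and 0.34 on day 7). They settle no direction. Klf4 differed by 0.54 and 0.08, with its 3 probes from -0.44 to 0.54 and from 0.08 to 1.33, and Myc by -0.08 on day 4. The factors' median was -0.05 on day 4 (percentile 36.3) and 0.08 on day 7 (percentile 58.3). The detected pluripotency genes, 6 on day 4 and 7 on day 7 of the 18 on the array, had medians of 0.54 (percentile 97.1) and 0.42 (percentile 97.3). With no detection filter all 18 gave 0.05 and 0.00 (percentiles 56.2 and 66.4), and the 4 detected on both day 7 arrays gave 0.07 (percentile 77.7). Dppa5a was at least 3.25-fold higher with DAPT on day 7, L1td1 differed by 0.92 and 0.42, Klf2 by 0.63 and -0.09, and Sall4 was at least 1.55-fold higher on day 7.

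The medians of the other lists with DAPT follow, for day 4 and then day 7. On day 7 those of the p53 targets and of the mesenchymal and fibroblast genes lay beyond the outer 2.5 percentiles. Wound and stress keratinocyte genes had medians of 0.11 and 0.08 (percentiles 62.5 and 91.6), with S100a9 at 1.93 and -0.14 and Hbegf at -1.38 on day 4. Simple epithelial and junction genes had medians of -0.10 and -0.04 (percentiles 11.4 and 52.9), with Krt19 at -1.5 and 0.24 and Ovol1 at 0.88 and 0.79. The p53 targets had medians of 0.24 and -0.22 (percentiles 88.7 and 1.11), and the second was 0.011 with median scaling and at percentile 24.3 with the mean over probes. Btg2 stood at 1.63 and -0.48, and Phlda3 at -0.92 and 1.03. Mesenchymal and fibroblast genes had medians of -0.06 and 0.16 (percentiles 13 and 99.5), with S100a4 at 1.24 and Col1a1 at -0.23 on day 7. Immune cell genes had medians of -0.16 and -0.50 (percentiles 16.2 and 2.63) over 4 detected members, among them Cd3e at -0.43 and -0.73. The endothelial medians were -0.19 and -0.10 (percentiles 23.2 and 44.4), with Emcn at -0.65 on day 7. Inflammatory cytokine genes had medians of 0.05 and -0.04 (percentiles 37.0 and 56.2), with Il6 at 1.01 on day 4 and Ptgs2 at 0.65 and -0.99. Unfolded protein and amino acid stress genes had medians of 0.05 and 0.11 (percentiles 41.0 and 94.9), with Ddit3 at -1.16 on day 4. For sterol synthesis genes they were 0.08 and 0.10 (percentiles 47.4 and 92.8), with Idi1, the relative of Idi2, at 0.68 and -0.26. For hypoxia and glycolysis genes they were 0.17 and -0.13 (percentiles 64.1 and 25.4), with Ndrg1 at 1.51 on day 4, its other probe at 0.20. For antioxidant genes they were -0.06 and -0.23 (percentiles 19.9 and 4.72), with Hmox1 at -1.31 and -0.70. Median scaling turned the sign of the hypoxia medians on both days, of the stress median on day 4, and of the junction, cytokine and endothelial medians on day 7.

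Between day 4 and day 7, the medians of proliferation and basal keratinocyte genes were lower and that of mesenchymal and fibroblast genes was higher. The 14 G2 and M phase genes had a median of -1.22 without DAPT and -0.93 with DAPT, and the 15 S phase genes -1.0 and -0.55, all at percentile 0. Basal keratinocyte genes had medians of -0.77 and -0.70 (both percentile 0), with Krt5 at -2.92 and -2.23, Col17a1 at -2.07 and -1.96 and Trp63 at -0.99 and -1.11. Without DAPT 4 of the 14 were above 0, among them Itgb1 at 0.76, with its other probe at -0.14, and Dst at 0.69. Wound and stress keratinocyte genes had medians of -0.46 (percentile 0.510) and -0.95 (percentile 0), with Krt6a, a keratin induced in wounds, at -2.66 and -1.61. Mesenchymal and fibroblast genes had medians of 0.56 and 0.66 (percentiles 99.8 and 100), with Col3a1 at 1.52 and 1.17 and Lum at 1.0 and 1.52. Without DAPT 3 of the 20 were at least 2-fold higher and 2 lower, Cdh2 at -1.84 and S100a4 at -1.04. The directions of these medians held in each scaling alternative. The interferon list had a median of -0.11 without DAPT (percentile 11.7) and 0.81 with DAPT (percentile 100). Melanocyte genes had medians of 0.66 (percentile 97.3) and -0.90 (percentile 0.0950), the second of which was -0.03 with no detection filter and held Ednrb at 1.98.

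Without DAPT, 1390 of 9879 genes differed at least 2-fold between the days, 740 higher and 650 lower on day 7; with DAPT it was 505 of 9860, 303 higher and 202 lower. Median scaling gave 332 and 1217 without DAPT and 427 and 129 with DAPT, with a shift of all genes by -0.23 and 0.13. The highest without DAPT were Npy, a neuropeptide, at 4.26, Prelp at 3.15, Mgp at 3.11, Ednrb at 3.07, Krt27 at 2.88 and Ecrg4 at 2.85. With DAPT they were Prelp at 3.79, Apod at 3.67, Npy at 3.46, Pamr1 at least 7.86-fold, Itga11 at 2.87 and Mylk at 2.72. The lowest without DAPT were Serpinb2 at -3.67, Igfbp3 at -3.15, Blmh at -3.06, Rbm3 at -2.97, Kctd5 at -2.94 and Krt5. With DAPT they were Klra4 at -2.97, Klra16 at -2.85, Plekhs1 at least 6.46-fold lower, Wfdc18 at -2.64, the cytokine gene Tslp at -2.50 and Clu at -2.43. Both comparisons, which share no array, had 128 genes higher, where independent lists would share 22.9, and 61 lower, where 12.5 would be shared.

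In the additive limma test, 190 genes passed for day over both treatments, of which 120 rose and 70 fell by day 7, and 975 passed an unadjusted p of 0.05, where chance would give 518. Npy rose by 3.86 (SE 0.38, adjusted p = 1.13e-19), Prelp by 3.47, Itga11 by 2.67, Pamr1 by 2.62 and Ednrb by 2.52. The size for Pamr1 is not exact, because its probe was not above background on day 4 with DAPT. Serpinb2 fell by 2.79 (adjusted p = 1.32e-09), Krt5 by 2.58, Clu by 2.53, Kctd5 by 2.38 and Klra4 by 2.35. The test left 0 genes with median scaling, without background correction or with no detection filter. With DAPT left out of the model, 1 gene passed on all 4 arrays, 1 without the untreated day 4 array, 263 without the DAPT day 4 array, 111 without the untreated day 7 array and 117 without the DAPT day 7 array.

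**Figure D3:**
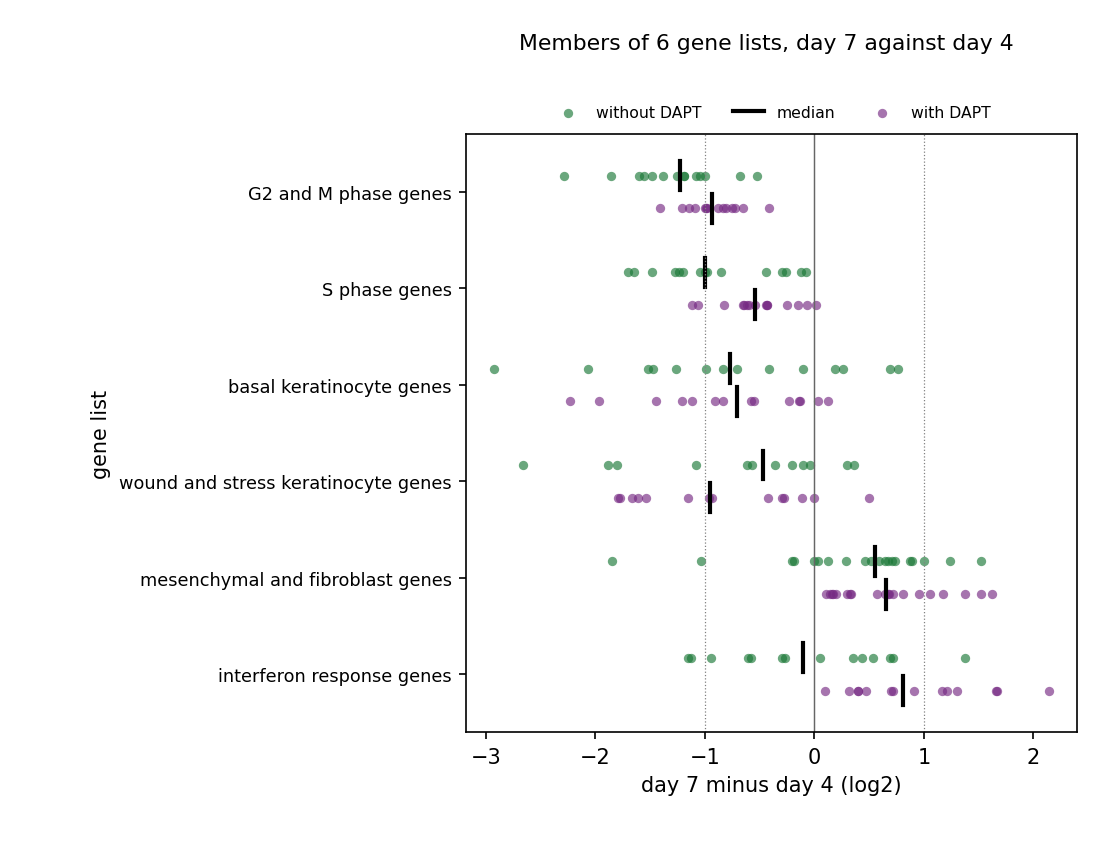
Log2 difference between day 7 and day 4 for each detected member of 6 gene lists (points), without DAPT (green) and with DAPT (purple), 1 array per group, with the list median as a black bar and dotted lines at 2-fold. The G2 and M phase medians were -1.22 and -0.93, the mesenchymal medians 0.56 and 0.66, and the interferon medians -0.11 and 0.81.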

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

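All tests in this part except the one of expression level and the one of disagreement between probes were chosen after the results they bear on had been seen, and the test of cell types on day 7 alone was added after the one over both days left the question open. The differences with DAPT ran in opposite directions on the 2 days for many genes, and with 1 array per group this difference between days was not tested. At least 2-fold lower on day 4 and at least 2-fold higher on day 7 were 49 genes, where independent lists would share 5.98, and 3 went the other way, where 1.66 would be shared. The first count was 140 with median scaling (24.7 expected), 96 with the authors' values (17 expected) and 14 with an offset of 50 (1.26 expected), and the second was 34 with the authors' values (15.4 expected). Among the named genes, the day 7 difference minus the day 4 difference was 3.96 for Syngr2, 3.73 for Rab1b, 3.19 for Atf4, 2.86 for Aph1a, 2.84 for both Sesn2 and Phgdh, 2.52 for Pfkp, 2.17 for Cdh2 and -2.80 for Wfdc18. The values for Sesn2 and Phgdh are not exact, because neither was above background on day 7 without DAPT.

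For this opposition, 20 bins of mean expression held 0.780% of the variance of the contrast between days across genes. That share cannot decide on a normalization curve acting on expression level. Quantile normalization of the 4 arrays together makes their distributions equal, which by itself leaves little contrast by level. The r between the days was negative under each alternative, from -0.25 to -0.32. With median scaling it was -0.32, so the opposition was present without the quantile step. The values go with effects on single probes. For these the contrast was divided by 2, which gives it the same noise as the mean DAPT effect. Probes of 1 gene then disagreed 1.68 times as much along it as along the mean DAPT effect (95% bootstrap interval 1.60 to 1.77, 1670 genes with 2 detected probes). Array brightness (RNA input, labelling or RNA quality) cannot be told apart from a response to DAPT that depends on the day, because the log2 brightness difference with DAPT, 0.73 higher on day 7 than on day 4, follows the same contrast. A change of transcript level also stays open for part of the opposition: probes of a gene still correlated at 0.332 across genes (interval 0.285 to 0.380). The correlation was 0.441 for the mean DAPT effect (interval 0.375 to 0.499) and 0.663 for the mean day effect. The gap to the mean day effect was first taken as evidence against a change of transcript level. It was then set aside, because a smaller shared change would give it too.

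The second pattern is the higher medians with DAPT of cornified and of G2 and M phase genes on both days and of S phase genes on day 7. Array brightness was lower with DAPT on day 4. The day 4 medians of the cornified and the G2 and M phase genes still had bootstrap intervals above 0 (from 0.12 and 0.21). These bounds cannot decide on array brightness, because they measure the spread among genes and not the error of an array. Median scaling also shifted the median of all genes by -0.18 on day 4, a larger step than the bound of 0.12 for the cornified genes. Array brightness thus stays open for both lists. It stays open for the S phase genes too, whose interval ran from -0.065 to 0.50. A lower share of all other cell types in the DAPT cultures, with falls by like amounts, was examined on the melanocyte and mesenchymal lists. On the day 7 arrays their falls were unlike: the melanocyte median lay -1.42 from the mesenchymal one (intervals -1.95 to -0.23 and -0.00 to 0.27). Log2 levels without and with DAPT were 9.18 and 6.94 for Tyrp1 and 13.18 and 13.27 for Dcn. The 4 detected immune cell genes had a day 7 median of -0.50 (percentile 2.63), with 1 of them above 0. This cannot decide on the cultures, because the intervals do not measure the error of an array. In the mean of both days the gap was -0.70 and the intervals met (-1.08 to -0.04 and -0.08 to 0.14). A lower share of all other cell types thus stays open, as does a change in melanocytes alone. These intervals resample genes of single arrays, and 3 of the 6 melanocyte genes on day 7 were at a bound. Unequal falls of single cell types were not tested and stay open. A response to DAPT stays open and has no replicate.

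The third pattern is the higher interferon response genes with DAPT on day 7. Array brightness stays open: the day 4 median had an interval of -0.31 to 0.38, with 8 members above 0 and 6 below, among them Cxcl10 at -0.96 and Bst2 at -0.72. A first bound on the percentile of that median was set aside, because members that go both ways exclude nothing. A difference between 2 single cultures, such as in their response to the transduction, and a response to DAPT were not tested against each other and both stay open.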

How the results depend on the processing

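The count that required every detected probe to pass was chosen after seeing the data. It gave 566, 181, 1122, 446 and 17 genes for DAPT on day 4, DAPT on day 7, day 7 against day 4 without and with DAPT, and both days together, against 735, 214, 1390, 505 and 21. Detection on every array compared, no detection filter, a detection threshold of 0.05 and the mean over probes left these 5 counts within 1.5 times. In the same order, a 1.5-fold threshold gave 2748, 1278, 3741, 1941 and 139 genes and an offset of 50 gave 363, 75, 786, 249 and 10. The directions follow by construction. The first admits smaller differences, and the second shrinks log2 differences, most of all for probes of low intensity. The authors' values gave 1259, 650, 1012 and 66 for DAPT on each day, for the days with DAPT and for both days together. Quantile normalization without background correction gave 1155, 455, 813 and 51 for the same 4. Median scaling gave 368 on day 7 with DAPT. The cause of these was not tested.

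The additive test for DAPT went from 12 genes to 0 without background correction, with median scaling, with no detection filter, with the mean over probes and with DAPT alone in the model, to 1 with an offset of 50 and to 2 with the authors' values. It gave 9 to 17 in the remaining settings, and from 0 to 0 with 1 array left out, where the lone array is assumed to vary like the others. There the other factor is also out of the model, so the array and the factor are not separated. The test for day went from 190 to 0 without background correction, with median scaling and with no detection filter, to 82 with an offset of 50, to 40 with the mean over probes and to 1 with day alone in the model. It gave 149 to 225 in the remaining settings and ranged from 1 to 263 with 1 array left out. The cause was not tested. At an unadjusted p of 0.05, between 93 and 337 genes passed for DAPT, fewer than chance would give in each setting with all 4 arrays (413 to 830), and between 653 and 1170 passed for day, more than chance would give. With 1 array left out, these were 79 to 975 and 595 to 2409, where chance would give 518. Of the list medians beyond the outer 2.5 percentiles, that of p53 targets with DAPT on day 7 turned, to 0.011 with median scaling. For named genes 3424 values moved by less than the SD between probes of a gene and 246 by more, and none of the differences of at least 2-fold turned. Signal over background limits the Notch targets, the reprogramming factors and the melanocyte genes, several of which lay near the lowest detected signal.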

Other observations

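The test of the chromosome 3 gene cluster below was chosen after some of its members had been seen. Several genes outside the lists stood out with DAPT on both days: Tgfbr3, a co-receptor for transforming growth factor beta, Slc1a3, a glutamate transporter (1.13 and 1.03), Bex1 (1.14, and on day 7 not detected without DAPT), Kif15, a mitotic kinesin (1.24 and 1.03), and Cyb5r2 (1.02 and 1.05). They were chosen after their values were seen.

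A hypothesis was that the genes of the epidermal differentiation complex, a cluster of neighbouring skin barrier genes on chromosome 3, rise together with DAPT. In the gene table of assembly GRCm38.p6, 29 detected genes outside the fixed lists lie from S100a1 to S100a11. Of these, 13 (44.8%) were at least 1.5-fold higher in the mean over both days and 0 at least 1.5-fold lower, against 3.08% of 10359 detected genes higher; the share set for a rise of the cluster, over 50%, was not reached. On day 4 alone 17 were at least 1.5-fold higher and 3 lower, such as Pglyrp3 at -1.18 and S100a16 at -0.99, and on day 7 alone 7 were higher and 2 lower, such as Lce1l at -0.64 after 1.54 on day 4. Apart from Tchhl1 (1.1) and Prr9 (1.05), these 13 were of the Lce and Sprr families, whose probes may cross-react within a family. Examples were Sprr2i at 1.84, Lce1a2 at 1.78 and Lce1d at 1.47. The value of Lce1a2 is not exact, because its probe was not above background on day 4 without DAPT. S100 genes such as S100a6 (0.32, but 1.02 on day 4) and S100a11 (0.07) stood lower. The S100 genes S100a9 (0.89) and S100a8 (0.48) belong to the fixed wound and stress list and so were not among the 29. These examples were chosen after their values were seen.

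The 5 probes of Actb, which encodes beta-actin, went apart. With DAPT, 2 of them differed by 1.75 and 1.71 on day 4 and by -2.60 and -2.67 on day 7, another by -1.75 and 1.19, and the brightest by -0.03 and -0.11. Actb was chosen after its values were seen. Among genes at least 2-fold different with DAPT on day 4 that had more than 1 detected probe, 56 of 217 had a probe in the opposite direction, and on day 7 this was 9 of 55. For day 7 against day 4 it was 107 of 386 without DAPT and 5 of 103 with DAPT.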
